A study of Danio rerio with 52 samples.

How the data were processed

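The study deposited 52 Affymetrix zebrafish gene arrays of 75212 probe sets, each hybridized with RNA from cells sorted by flow cytometry. Larvae were 4 days old, each sample came from about 50 skins, 1 ng of RNA was amplified, and RNA integrity numbers were above 8. Hair cells and double-positive mantle cells were pooled from several sorts. The deposited values, taken as log2 values, were made by the authors with RMA, and the labels also name Partek 6.6. The log base is not stated, and 2 was inferred from RMA and the range of the values. The values were used as they stand. They range from -1.29 to 15.05 with 0 missing. The authors left out a few samples of the untreated populations that stood apart in a principal component analysis, and the copper analysis was imported separately. The labels do not say whether replicates came from separate clutches or sorts, so p measures the spread between the samples as deposited. Leaving out samples that stood apart and pooling sorts could each make that spread smaller. Signal over background was not used here, and a filter on dim genes was tried as an alternative.

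Of the probe sets, 21661 are listed with a gene, 20806 of them with 1 gene symbol, 855 with several, and 53551 could not be named. For 20323 listed probe sets the Entrez ID was found in RefSeq, from which names alone were taken, and a symbol changed in 1 case. The 19260 genes tested include 1365 with more than 1 probe set, for which the probe set with the highest mean was used, and 2326 with placeholder symbols, which were counted but not named.

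Samples were grouped by sorted population, treatment and time, 12 groups in all. The comparisons, tests, gene lists, named-gene rule and a first set of alternatives were fixed before the data were examined. One linear model per gene was fitted with limma 3.58.1 (lmFit, then eBayes with default settings) in R 4.3.3, with the data.table package (version 1.17.8), and figures were drawn with matplotlib 3.10.9. The 17 untreated arrays formed one fit, with 5 comparisons of populations. The non-fluorescent and mCherry+ mantle arrays, 42 in number, formed the other. It gave each time against untreated cells in each population, and the difference of these responses between the populations. The p-values were adjusted by Benjamini and Hochberg over the genes of each comparison, and genes with an adjusted p below 0.05 were called. The hair cell group has 2 arrays and is assumed to vary like the others.

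Lists of 25 gene groups were written for pathways, stress responses and the cell types that skin could hold. Each was tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Members were also counted after adjustment over the list alone. The rule for named genes took up to 6 genes with the largest increases and 6 with the largest decreases in each comparison, among called genes whose groups do not overlap. For a difference of responses the overlap condition was left out. It added up to 3 called members of each list, and a fixed set whether called or not. That set was alpl, pou4f3, atoh1a and myo6b in untreated cells, and atoh1a, sox2, notch3, her4.1, lfng, dla, dld, fgfr1a, lef1, axin2, pcna, mmp9 and stat3 after copper. From the same set hsp70l and mt2 were not measured.

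After the data were examined, array means were found to differ between 3 sets of arrays, and the arrays of 3 h and 5 h to carry a constraint of an earlier adjustment. In the 16 treated mantle arrays the smallest singular value of the deviations from group means was 0.0013, the next 97.6. In the 19 treated non-fluorescent arrays they were 0.00137 and 86, and in the untreated arrays 10.4 and 65.3. A block term was therefore added as an alternative. Replicates 1 to 3 of the 3 h and 5 h groups formed a block of their own in each population. The untreated fit had 3 blocks: non-fluorescent replicates 5 and 6 with mCherry+ replicates 1 and 2, non-fluorescent replicate 1 with mCherry+ replicates 3 and 4, and the rest. In the untreated arrays the constraint is only approximate (10.4 against 65.3), so their block has a weaker basis. The file does not say which adjustment was made. Array median here means the median of the 19260 tested genes in an array, not that of all 75212 probe sets. Where setting these medians equal moved the median of all tested genes by more than 0.1, gene values are given relative to the array medians. The same was done in all differences of responses. In the other comparisons gene values are on the deposited scale.

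The alternatives chosen beforehand were array median centring, quantile normalization, a block for the replicate number, only the groups compared, all 52 arrays in 1 fit, no variance moderation, eBayes with trend and robust, array weights, the mean of the probe sets of a gene, all probe sets, dim genes left out, an adjusted p below 0.01, an estimated correlation, and leaving out each array. Added after the data were seen were the block for the earlier adjustment, that block with centring, averaging of close untreated pairs, and comparisons within the treated arrays. Called counts were compared with those from other splits of the same arrays. The steps were tested on simulated data, where 50 genes were changed by a given log2 step in the mCherry+ against non-fluorescent comparison. There 8, 37, 48 and 50 of them were recovered at log2 steps of 0.5, 1, 2 and 3. In simulated mantle arrays with no changed gene but the same adjustment, 74 genes were called between 3 h and 1 h without the block and 0 with it.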

Results

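The data are 52 gene expression arrays of cells sorted by fluorescence from the skins of 4-day-old zebrafish larvae, a tissue that carries the lateral line. Neuromasts, the sense organs of the lateral line, hold mechanosensory hair cells, support cells and an outer rim of mantle cells. Untreated larvae gave 4 populations, which were non-fluorescent cells (n = 6), mCherry+ mantle cells (n = 5), mCherry+/GFP+ mantle cells from a second transgenic line (n = 4) and GFP+ hair cells (n = 2). Copper, which kills hair cells, was given at 5 µM for 1 h, and non-fluorescent cells were collected 1 h (n = 7), 3 h, 5 h and 11 h later (n = 4 each). The mCherry+ mantle cells were collected at the same 4 times (n = 4 each). The number of arrays limits the precision of every value. Each of 19260 genes was tested, and a gene counted as called at an adjusted p below 0.05 in limma. Counts refer to the deposited values unless another scale is given. A gene named as higher or lower was called, in the same direction, in 4 fits: on the deposited values, with array medians set equal, after quantile normalization, and with array medians set equal plus a block term for an earlier adjustment of the values. Exceptions are marked. Single-gene changes are log2 differences ± SE, and list levels are log2 means ± SD.

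The first question was how mantle cells, candidate progenitors of hair cells, differ from the other skin cells. Relative to the array medians, mCherry+ mantle cells (n = 5) held more aplnra, an apelin receptor, than non-fluorescent cells (n = 6), by 5.47 ± 0.49. They also held more ucp1, a mitochondrial uncoupling protein (5.09 ± 0.30), anos1a, the matrix protein anosmin (4.89 ± 0.23), and robo3, a receptor of the Slit pathway (4.59 ± 0.17). Large decreases were in the transporter gene abcb5 (-5.77 ± 0.50), in rhag, a red blood cell glycoprotein (-5.61 ± 0.21), and in the epidermal annexin gene anxa1b (-5.45 ± 0.35). For each of these genes the arrays of the populations did not overlap. Of the 28 measured members of the neuromast support and mantle cell list, 14 were higher, 3 lower and 11 not called, with 14 and 3 adjusted over the list alone (camera adjusted p = 0.000111, adjusted p = 0.0436 with an estimated correlation). Among them were the homeobox gene hmx3a (3.86 ± 0.25), the tetraspanin gene TSPAN1 (3.68 ± 0.42) and the claudin gene cldne (-4.86 ± 0.30). The Fgf pathway list had 18 higher and 4 lower of 29, the same numbers adjusted over the list alone (camera adjusted p = 2.25e-06, adjusted p = 0.0115 with an estimated correlation), with fgf10a at 3.56 ± 0.13 and fgf2 at 3.50 ± 0.33. Of 48 Wnt pathway genes, 23 were higher and 4 lower (25 and 4 adjusted over the list alone; camera adjusted p = 5.05e-07, adjusted p = 0.0115 with an estimated correlation), among them the receptor gene fzd9b (3.14 ± 0.33) and wnt10a (2.32 ± 0.25).

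Lists of other skin cell types were mostly lower in mCherry+ mantle cells. Keratinocyte genes were lower in 26 of 35 and higher in 2, as they were adjusted over the list alone (camera adjusted p = 4.67e-13, adjusted p = 0.0442 with an estimated correlation), and the keratin gene krt97 changed by -5.35 ± 0.49. Schwann cell and glia genes were lower in 12 of 16 and higher in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 2.25e-06, adjusted p = 0.0115 with an estimated correlation), with myelin basic protein, mbpa, at -3.25 ± 0.40. For muscle the count was 33 lower of 34, also 33 adjusted over the list alone, and that call was lost with the other correlation setting (camera adjusted p = 1.54e-17, adjusted p = 0.0767 with an estimated correlation). Connective tissue genes went both ways, with 12 higher and 9 lower of 34 (14 and 9 adjusted over the list alone; camera adjusted p = 0.0714, adjusted p = 0.653 with an estimated correlation), and the matrix gene fbln1 was among the higher ones (3.72 ± 0.23). Ribosome biogenesis genes were lower in 41 of 47 and higher in 0 (44 and 0 adjusted over the list alone; camera adjusted p = 1.21e-14, adjusted p = 0.0115 with an estimated correlation), such as rrp9 (-1.5 ± 0.20) and nop2 (-1.34 ± 0.19). The reporter gene's own locus alpl differed by 0.52 ± 0.17 relative to the array medians (adjusted p = 0.0203) and by 0.37 on the deposited scale (adjusted p = 0.105). The hair cell genes pou4f3 and atoh1a were not called, at 0.23 ± 0.15 and 0.41 ± 0.19, and myo6b, a hair cell myosin, was higher by 2.11 ± 0.18. In all, 6216 genes were called (2912 higher, 3304 lower), and 4840 in all 4 fits (2811 higher, 2029 lower). On the deposited values the median difference of all genes was 0.0125. Setting array medians equal moved it further from no difference, by 0.153. The higher share of calls went from 46.8% to 65.6% (4666 higher, 2452 lower). Medians over all probe sets overlapped, at 3.69 to 3.74 in untreated non-fluorescent and 3.70 to 3.75 in untreated mCherry+ arrays.

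Mantle cells carrying both mCherry and GFP (n = 4) were set against the same non-fluorescent cells (n = 6), again relative to the array medians. TSPAN1 was higher by 7.20 ± 0.45, anos1a by 7.13 ± 0.25 and the atypical cadherin gene fat1b by 6.58 ± 0.22. Of 28 neuromast support and mantle genes, 19 were higher and 2 lower (19 and 3 adjusted over the list alone; camera adjusted p = 6.57e-13, adjusted p = 0.00226 with an estimated correlation). These included hmx3a (5.78 ± 0.26) and hmx2 (5.56 ± 0.28), homeobox genes of the ear and lateral line. Wnt pathway genes were higher in 26 of 48 and lower in 6 (29 and 6 adjusted over the list alone; camera adjusted p = 1.8e-08, adjusted p = 0.0105 with an estimated correlation), among them wnt3 (3.91 ± 0.32) and wnt2 (3.30 ± 0.26). The Notch pathway had 12 higher and 3 lower of 33 (13 and 5 adjusted over the list alone; camera adjusted p = 0.0137, adjusted p = 0.13 with an estimated correlation), including the receptor gene notch3 (2.58 ± 0.21) and the target gene her4.1 (2.47 ± 0.42). Here alpl was higher, by 1.36 ± 0.18, as was myo6b (1.45 ± 0.20), while pou4f3 (0.02 ± 0.16) and atoh1a (0.52 ± 0.20) were not called. Lower genes included rhag (-5.62 ± 0.22), the collagen gene col6a2 (-5.08 ± 0.21) and the chemokine gene cxcl12a (-4.55 ± 0.21). Members of the connective tissue list were lower in 21 of 34 and higher in 5, unchanged in number adjusted over the list alone (camera adjusted p = 0.00087, adjusted p = 0.458 with an estimated correlation). Glia genes were lower in 9 of 16 (12 adjusted over the list alone; camera adjusted p = 2.12e-05, adjusted p = 0.0114 with an estimated correlation). The total was 6044 calls (2697 higher, 3347 lower), of which 4142 stood in all 4 fits (2250 higher, 1892 lower). The median of all genes was -0.0569 on the deposited values and moved by 0.112 with array medians set equal. The higher share of calls went from 44.6% to 56.7% (3422 higher, 2610 lower).

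Hair cells (n = 2) differed from non-fluorescent cells (n = 6) in most genes of their own list. Of 38 measured hair cell genes, 30 were higher, 0 lower and 8 not called, with the same numbers adjusted over the list alone (camera adjusted p = 2.7e-25, adjusted p = 6.25e-05 with an estimated correlation). The reporter's source gene pou4f3, a transcription factor of hair cells, was higher by 5.61 ± 0.21, myo6b by 5.32 ± 0.25, the calcium pump gene atp2b2 by 6.29 ± 0.19 and the ciliary gene tekt3 by 6.42 ± 0.45. Atoh1a, which specifies hair cells, was higher by 2.97 ± 0.26. The list mean was 7.54 ± 0.014 in hair cells (n = 2) and 4.2 ± 0.17 in non-fluorescent cells (n = 6). The 2 hair cell arrays lay close together (SD of their difference 0.43), and the labels do not say whether they are separate samples. Alpl was not called (0.39 ± 0.23). Cell cycle genes were lower in 35 of 45 (38 lower and 1 higher adjusted over the list alone; camera adjusted p = 3.57e-11, adjusted p = 0.0695 with an estimated correlation), for example ccnd1, which encodes cyclin D1 (-2.80 ± 0.21), and the replication helicase gene mcm4 (-2.77 ± 0.26). Connective tissue genes were lower in 30 of 34 (32 adjusted over the list alone; camera adjusted p = 3.28e-20, adjusted p = 0.0465 with an estimated correlation), with fmoda at -6.02 ± 0.53 and the mesenchymal homeobox gene prrx1a at -5.45 ± 0.31. Matrix remodelling genes were lower in 33 of 43 and higher in 2, also adjusted over the list alone (camera adjusted p = 5.2e-11, adjusted p = 0.0405 with an estimated correlation), and ribosome biogenesis genes were lower in 38 of 47 (41 adjusted over the list alone; camera adjusted p = 1.3e-10, adjusted p = 0.0405 with an estimated correlation). Of 50 ribosomal protein genes, 43 were lower (44 adjusted over the list alone; camera adjusted p = 5.72e-11, adjusted p = 0.0582 with an estimated correlation).

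Markers of pigment cells stood out within the hair cell sort. A large increase was in gch2, an enzyme of pteridine pigment synthesis (8.01 ± 0.26), and xdh, which acts in the same pathway, was higher by 4.47 ± 0.22. Of 21 pigment cell genes, 11 were higher and 6 lower, the same adjusted over the list alone (camera adjusted p = 0.00268, adjusted p = 0.134 with an estimated correlation). The pigment list mean was 5.62 ± 0.048 in hair cells (n = 2) and 4.34 ± 0.20 in non-fluorescent cells (n = 6). The hair cell comparison called 6988 genes (2979 higher, 4009 lower), with 5536 in all 4 fits (2656 and 2880). It rested on 2 hair cell arrays, and without replicate 1 of the hair cells the count was 4637.

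Hair cells (n = 2) and mCherry+ mantle cells (n = 5) were compared to separate the sensory cells from their candidate progenitors. Hair cell genes were higher in 31 of 38 and lower in 1, also adjusted over the list alone (camera adjusted p = 1.25e-22, adjusted p = 0.000115 with an estimated correlation). Pou4f3 was higher by 5.53 ± 0.22, atoh1a by 2.71 ± 0.27, the otoferlin gene otofb by 6.56 ± 0.37 and the transcription factor gene gfi1aa by 6.34 ± 0.28. Mantle cells held more of several signalling genes. Wnt pathway genes were lower in hair cells in 29 of 48 and higher in 3 (32 and 3 adjusted over the list alone; camera adjusted p = 3.31e-10, adjusted p = 0.00461 with an estimated correlation), with fzd9b at -4.92 ± 0.48 and nkd1, a feedback inhibitor, at -4.91 ± 0.25. Fgf pathway genes were lower in 16 of 29 and higher in 3, the same adjusted over the list alone (camera adjusted p = 2.11e-05, adjusted p = 0.0202 with an estimated correlation), including the receptor gene fgfr4 (-5.30 ± 0.29). Matrix remodelling genes were lower in 30 of 43 (31 adjusted over the list alone; camera adjusted p = 1.77e-13, adjusted p = 0.0128 with an estimated correlation), and tgfbi, a secreted matrix protein, differed by -7.43 ± 0.36. Connective tissue genes were lower in 26 of 34, also adjusted over the list alone (camera adjusted p = 8.91e-18, adjusted p = 0.0556 with an estimated correlation), such as prrx1a (-6.96 ± 0.32). The pigment genes gch2 (7.69 ± 0.26), kita (5.32 ± 0.38) and csf1ra (4.56 ± 0.45) were among 12 of 21 pigment genes that were higher in hair cells, with 4 lower (12 and 5 adjusted over the list alone; camera adjusted p = 0.00353, adjusted p = 0.225 with an estimated correlation). Alpl did not differ by the test (0.03 ± 0.23). There were 6864 calls (3395 higher, 3469 lower), 5248 of them in all 4 fits (2421 higher, 2827 lower).

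The mantle populations of the transgenic lines differed from each other. Cells with both reporters (n = 4) held more TSPAN1 than mCherry+ cells (n = 5), by 3.56 ± 0.47, and more of the neural and placodal factor sox3 (2.55 ± 0.28) and of cldnb, a claudin of the lateral line (2.22 ± 0.31). Neuromast support and mantle genes were higher in 19 of 28 and lower in 3, also adjusted over the list alone (camera adjusted p = 7.98e-09, adjusted p = 0.0142 with an estimated correlation), and alpl was higher by 0.88 ± 0.19. The list mean was 7.52 ± 0.20 (n = 4) in double-positive and 6.49 ± 0.055 (n = 5) in mCherry+ cells, against 5.69 ± 0.093 (n = 6) in non-fluorescent cells. Notch pathway genes were higher in 12 of 33 and lower in 2 (13 and 2 adjusted over the list alone; camera adjusted p = 0.00502, adjusted p = 0.2 with an estimated correlation), with notch3 at 2.02 ± 0.23 and nrarpa, a feedback target of Notch, at 1.69 ± 0.29. Keratinocyte genes were higher in 21 of 35 and lower in 1, also adjusted over the list alone (camera adjusted p = 1.47e-09, adjusted p = 0.2 with an estimated correlation), such as the envoplakin gene evpla (3.79 ± 0.31). Connective tissue genes were lower in 23 of 34 and higher in 1 (26 and 1 adjusted over the list alone; camera adjusted p = 2.32e-10, adjusted p = 0.239 with an estimated correlation), with col6a2 at -4.12 ± 0.23, col6a1 at -4.03 ± 0.24 and twist1b, a mesenchymal factor, at -2.67 ± 0.29. The heart and mesoderm factor tbx20 was lower, at -4.76 ± 0.23, and notum1a, a secreted Wnt inhibitor, at -3.67 ± 0.38. Pou4f3 (-0.17 ± 0.17) and atoh1a (0.14 ± 0.21) were not called. The count was 4880 (2423 higher, 2457 lower), with 2562 in all 4 fits (1121 higher, 1441 lower) and 2552 with the block term on the deposited values.

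**Figure D1:**
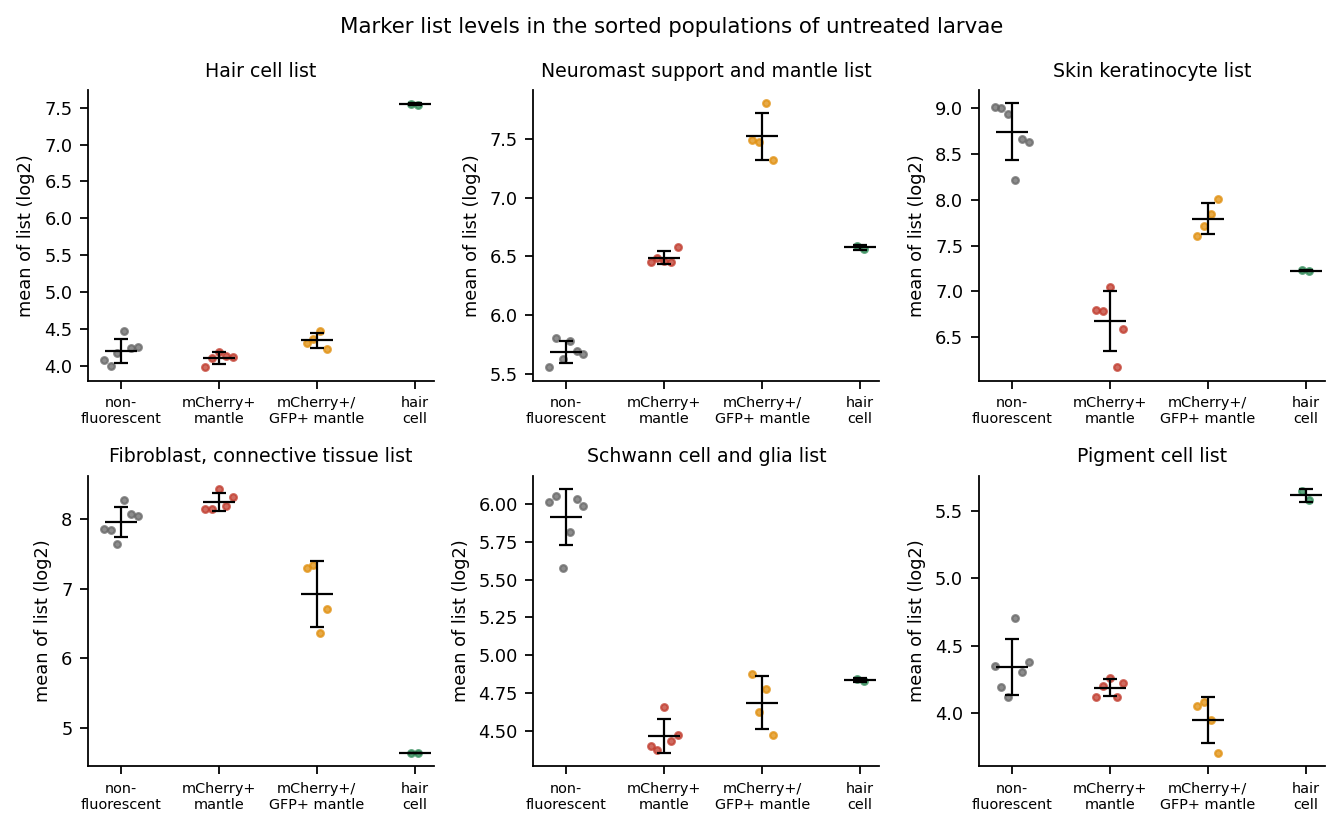
Mean log2 level of each marker list (vertical axis) in the arrays of the 4 sorted populations of untreated larvae (horizontal axis); points are arrays, black bars the mean ± SD. The hair cell list lies at 7.53 to 7.55 in both hair cell arrays and at most at 4.47 in the other arrays.

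The copper series asked how mantle and other skin cells change while hair cells are lost and begin to return. Array means differed between 3 sets of arrays. They were 4.27 to 4.30 in the 17 untreated arrays, 4.45 to 4.48 in the 19 copper-treated non-fluorescent arrays and 4.29 to 4.37 in the 16 copper-treated mantle arrays. The ranges of the untreated and the treated mantle arrays meet at 4.29 to 4.30. Each set holds treated or untreated arrays alone, so a set and the treatment cannot be told apart. Across probe sets, the deviations of replicate 4 from the group mean at 3 h and at 5 h mirrored each other in both populations (r = -1 across probe sets, which are not independent replicates). A block term for replicates 1 to 3 of the 3 h and 5 h groups was therefore also fitted, and with it the level at these times rests on the replicate 4 arrays. Within the treated mantle arrays, 2071 genes were called between 3 h and 1 h (122 with the block), and 2060 between 5 h and 1 h (133 with the block). Without replicate 1 or 4 of the 3 h mantle group the first count was 1325 or 1335, and without replicate 4 of the 5 h mantle group the second was 1252. Limma called 0 genes between 11 h and 1 h (1687 at an unadjusted p under 0.05; 1 call without replicate 2 of the 1 h mantle group), and 0 between 5 h and 3 h (1420 at an unadjusted p under 0.05). In non-fluorescent cells 3043 genes were called between 3 h and 1 h (247 with the block; 1954 without replicate 4 of the 3 h group). Between 5 h and 1 h it was 2728 (211 with the block; 1817 and 1593 without replicates 2 and 3 of the 5 h group). For 11 h against 1 h the count was 16. It became 26, 25 and 54 without replicates 2, 3 and 7 of the 1 h group, and 2, 3, 8 and 67 without replicates 1, 2, 3 and 4 of the 11 h group. Between 5 h and 3 h only olah, a gene of fatty acid synthesis chosen after its value was seen, was called (1.53 ± 0.22, adjusted p = 0.0272), and 0 genes with the block (1912 at an unadjusted p under 0.05 in limma). That count was 6, 0 and 0 without replicates 2, 3 and 4 of the 3 h group, and 2, 0, 0 and 0 without replicates 1, 2, 3 and 4 of the 5 h group.

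**Figure D2:**
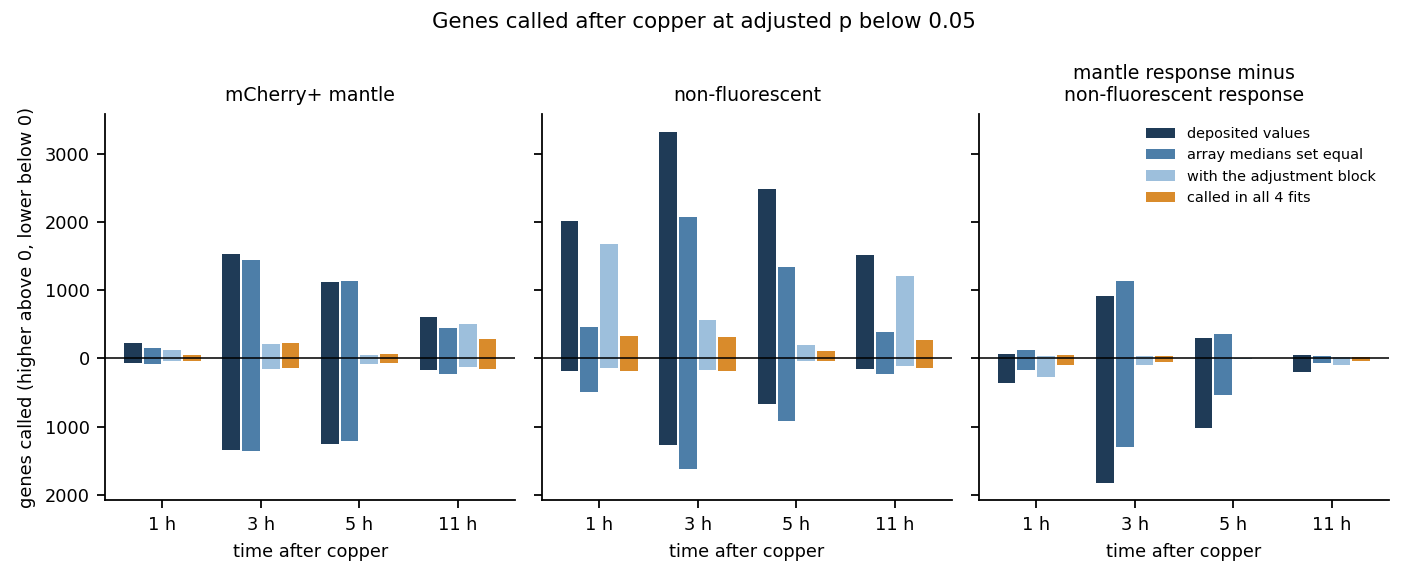
Number of genes called at an adjusted p below 0.05 (vertical axis, higher genes above 0 and lower genes below) by time after copper (horizontal axis) in mCherry+ mantle cells, in non-fluorescent cells and for the difference of their responses. Bars are the deposited values, array medians set equal, the block term on the deposited values, and genes called in all 4 fits; at 3 h in mantle cells these are 2878, 2795, 360 and 360 genes.

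At 1 h after copper, mantle cells (n = 4) differed from untreated ones (n = 5) in few genes. Wnt3, a Wnt ligand, was higher by 1.40 ± 0.30 (limma adjusted p = 0.0115), the transcription factor gene klf3 by 2.12 ± 0.28 and tmem30b, a lipid flippase subunit, by 1.80 ± 0.38. Cebpd, an early stress-response factor, was higher by 1.12 ± 0.21. The Notch effector hey1 was lower, at -1.53 ± 0.31, as were the apoptosis gene diabloa (-1.83 ± 0.37) and the mitochondrial ribosome gene mrpl30 (-1.86 ± 0.35). Of 35 keratinocyte genes, 2 were higher and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 3.85e-05, adjusted p = 0.458 with an estimated correlation). Their mean was 7.33 ± 0.50 (n = 4) against 6.68 ± 0.33 (n = 5) in untreated cells. Erythrocyte genes had 0 higher and 0 lower of 16 (1 lower adjusted over the list alone; camera adjusted p = 4.52e-06, adjusted p = 0.451 with an estimated correlation). Their mean was 3.42 and 3.35 in untreated replicates 1 and 2 and 4.60 to 5.08 in replicates 3 to 5. At 1 h it was 3.49 to 3.62 in replicates 1 to 3 and 2.08 in replicate 4. Atoh1a (0.22 ± 0.19), sox2 (-0.54 ± 0.34), notch3 (0.38 ± 0.21), lef1 (0.15 ± 0.23) and stat3 (0.38 ± 0.26) were not called. The count was 289 (221 higher, 68 lower), 84 of them in all 4 fits (45 higher, 39 lower), and 174 with the block. The higher share was 76.5% and 66.7% with array medians set equal (152 higher, 76 lower). The count dropped to 144, 181, 121 and 113 without untreated replicates 2, 3, 4 and 5, and to 124 and 108 without replicates 3 and 4 at 1 h. Untreated replicates 1 and 2 lie close together, and with such close pairs averaged the count was 144.

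At 3 h after copper, mantle cells (n = 4) were compared with untreated cells (n = 5). Mmp30, a matrix metalloproteinase, was higher by 3.66 ± 0.73, fn1b, a fibronectin, by 2.43 ± 0.38, ptgs2a, a cyclooxygenase, by 3.66 ± 0.58, and fgfbp1a, which binds Fgf proteins, by 3.63 ± 0.58. In mantle arrays at 3 h, mmp30 and the keratinocyte list mean were both highest in replicate 1 and lowest in replicate 4. Non-fluorescent arrays at 3 h held less mmp30 (mean 2.47 above the array median, against 4.51), though their keratinocyte mean was 8.58 to 9.08. Which cells of the mantle sort gave the mmp30 change was not tested. TSPAN1, which untreated mantle cells held more of than non-fluorescent cells, was lower, at -3.61 ± 0.42 (limma adjusted p = 3.64e-07), and fgf3 at -1.87 ± 0.30. Keratinocyte genes were higher in 18 of 35 and lower in 0 (23 and 0 adjusted over the list alone; camera adjusted p = 1.82e-11, adjusted p = 0.821 with an estimated correlation), and 5 were higher in all 4 fits. These included col17a1a, a hemidesmosome collagen (3.68 ± 0.73), and tp63, a factor of basal skin cells (2.38 ± 0.46), while cdh1, which encodes E-cadherin, was higher by 2.38 ± 0.46. The list mean was 8.07 ± 0.52 (n = 4) against 6.68 ± 0.33 (n = 5). Matrix remodelling genes had 9 higher and 2 lower of 43 (10 and 2 adjusted over the list alone; camera adjusted p = 0.354). Several markers of other skin cell types were called on the deposited values, but not with array medians set equal plus the block. Their adjusted p with that block is given after each value. Of the named ones, those with higher deposited values were hcls1 (2.02 ± 0.53; 0.138), arhgdig (1.95 ± 0.43; 0.068) and rac2 (1.27 ± 0.45; 0.309) of leukocytes, ca2 (1.73 ± 0.48; 0.167) of ionocytes and muc5.2 (2.1 ± 0.67; 0.249) of mucous cells. Also higher on the deposited values were mbpb (1.91 ± 0.40; 0.0635) and nrg1 (1.43 ± 0.38; 0.16) of glia, col1a2 (1.55 ± 0.41; 0.142) and col1a1b (1.52 ± 0.35; 0.0859) of connective tissue and neurod2 (0.48 ± 0.15; 0.251) of neurons. Those with lower values were twist2 (-1.41 ± 0.39; 0.186) of connective tissue, esama (-1.33 ± 0.39; 0.213) and fli1 (-1.08 ± 0.32; 0.238) of endothelium and isl2a (-1.43 ± 0.45; 0.255) and map1b (-0.83 ± 0.19; 0.114) of neurons. Higher and lower members of these lists, with the camera adjusted p, numbered 3 and 0 of 31 (0.497) for leukocytes, 1 and 0 of 20 (0.369) for ionocytes and 1 and 0 of 9 (0.318) for mucous cells. They were 2 and 0 of 16 (0.946) for glia, 3 and 6 of 34 (0.369) for connective tissue, 0 and 2 of 27 (0.946) for endothelium and 1 and 2 of 31 (0.946) for neurons. Protein folding genes were lower in 6 of 33 and higher in 1, also adjusted over the list alone (camera adjusted p = 0.029, adjusted p = 0.821 with an estimated correlation), among them the endoplasmic reticulum chaperones hsp90b1 (-1.92 ± 0.27) and hspa5 (-1.56 ± 0.27). In the metal and oxidative stress list, 5 of 39 were higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.728), such as the autophagy receptor sqstm1 (1.82 ± 0.23) and srxn1, a sulfiredoxin (-1.96 ± 0.26). The Wnt scaffold axin1 was lower, at -1.25 ± 0.20. Lfng, a Notch modulator (-1.26 ± 0.28), and atoh1a (0.62 ± 0.19) were called on the deposited values, but not with array medians set equal plus the block, at adjusted p = 0.0893 and 0.22. Mantle cells had 2878 calls (1539 higher, 1339 lower), 360 with the block and 360 in all 4 fits (221 higher, 139 lower).

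Mantle cells at 5 h (n = 4) still held less fgf3 (-1.84 ± 0.30) and hsp90b1 (-1.96 ± 0.27) than untreated cells (n = 5). The endoplasmic reticulum gene creld2 was lower, at -2.62 ± 0.27, dpagt1, which starts protein N-glycosylation, at -2.49 ± 0.34, and rrm1, a subunit of ribonucleotide reductase, at -1.52 ± 0.27. The autophagy gene atg2b was higher by 3.18 ± 0.56, sqstm1 by 1.23 ± 0.23 and the lysosomal nuclease gene dnase2 by 2.57 ± 0.38. Protein folding genes were lower in 7 of 33 (9 adjusted over the list alone; camera adjusted p = 0.000585, adjusted p = 0.554 with an estimated correlation). Cell cycle genes were lower in 6 of 45 and higher in 2 (11 and 2 adjusted over the list alone; camera adjusted p = 0.000585, adjusted p = 0.961 with an estimated correlation). Keratinocyte genes were higher in 6 of 35 (10 adjusted over the list alone; camera adjusted p = 3.19e-06, adjusted p = 0.961 with an estimated correlation), and none of these calls stood in all 4 fits (0 genes). Their mean was 7.60 ± 0.74 (n = 4) against 6.68 ± 0.33 (n = 5), with 6.58 in replicate 3 and 7.54 to 8.17 in the other arrays at 5 h, and 6.17 to 7.05 in untreated arrays. Markers of other skin cell types were again called on the deposited values, but not with array medians set equal plus the block. Their adjusted p with it follows each value. Of the named ones, higher values were in ca2 (1.79 ± 0.48; 0.178) of ionocytes, arhgdig (1.34 ± 0.43; 0.27) of leukocytes, mbpb (1.37 ± 0.40; 0.24) and nrg1 (1.12 ± 0.38; 0.321) of glia, casq1b (0.63 ± 0.19; 0.218) of muscle and prdm14 (0.55 ± 0.18; 0.284) of neurons. Lower values were in twist2 (-1.35 ± 0.39; 0.255), col6a2 (-1.3 ± 0.34; 0.205) and pdgfrb (-0.86 ± 0.28; 0.368) of connective tissue, myhz2 (-0.67 ± 0.20; 0.274) of muscle and galnt12 (-0.98 ± 0.29; 0.277) of mucous cells. Higher and lower members, with the camera adjusted p, numbered 1 and 0 of 20 (0.157) for ionocytes, 1 and 0 of 31 (0.696) for leukocytes and 2 and 0 of 16 (0.732) for glia. They were 1 and 1 of 34 (0.696) for muscle, 1 and 0 of 31 (0.792) for neurons, 0 and 4 of 34 (0.455) for connective tissue and 0 and 1 of 9 (0.948) for mucous cells. Atoh1a (0.94 ± 0.19), lfng (-1.51 ± 0.28) and the replication gene pcna (-1.15 ± 0.26) were called on the deposited values. With array medians set equal plus the block their adjusted p was 0.0626, 0.0608 and 0.128. The time point gave 2388 calls (1127 higher, 1261 lower), 137 with the block and 135 in all 4 fits (68 higher, 67 lower). It gave 1585 calls without untreated replicate 5 and 1541 without replicate 4 at 5 h.

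By 11 h after copper, mantle cells (n = 4) held more wnt3 (1.60 ± 0.30), fgfbp1a (3.21 ± 0.58), mmp30 (3.14 ± 0.73) and hmx3a (1.5 ± 0.36) than untreated ones (n = 5). For mmp30 the groups overlapped, with replicate 3 at 11 h at 1.73 above the array median and untreated replicate 3 at 2.34. Rac2, a small GTPase of leukocytes, was higher by 2.41 ± 0.45 and hcls1, also of leukocytes, by 2.01 ± 0.53. The leukocyte list had 2 higher and 0 lower of 31 (3 and 0 adjusted over the list alone; camera adjusted p = 0.263). Markers of other cell types that were lower were col6a1 of connective tissue (-0.83 ± 0.21), tnnt3b of muscle (-1.61 ± 0.37) and trpm1b of pigment cells (-0.59 ± 0.17). Col6a2 was called on the deposited values, but not with array medians set equal plus the block (-1.14 ± 0.34; adjusted p = 0.0532). Higher and lower members, with the camera adjusted p, numbered 0 and 2 of 34 (0.0677) for connective tissue and 0 and 1 of 21 (0.0677) for pigment cells. For muscle it was 0 and 1 of 34 (camera adjusted p = 1.21e-06, adjusted p = 0.602 with an estimated correlation). The muscle list mean was 3.27 in replicate 4 at 11 h and 3.89 to 4.02 in the other arrays at that time. In untreated mantle arrays it was 3.98 to 4.52. The secreted Wnt inhibitors notum1a (-1.53 ± 0.40) and sfrp2 (-1.35 ± 0.30) were lower, as was cldn19, a claudin of myelinating glia and tight junctions (-2.18 ± 0.52). A pair of copper chaperones was lower, cox17, which serves cytochrome oxidase (-1.21 ± 0.26), and ccs, which serves superoxide dismutase (-1.06 ± 0.31); the list that holds them had 0 higher and 2 lower of 39 (also adjusted over the list alone; camera adjusted p = 0.852). Neuromast support and mantle genes were higher in 4 of 28 and lower in 0 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0232, adjusted p = 0.602 with an estimated correlation), ackr3b, a chemokine-scavenging receptor, among them (1.02 ± 0.18). Keratinocyte genes were higher in 10 of 35 (16 adjusted over the list alone; camera adjusted p = 2.91e-08, adjusted p = 0.602 with an estimated correlation), with the laminin gene lamb4 at 2.50 ± 0.52. Their mean was 7.61 ± 0.23 (n = 4) against 6.68 ± 0.33 (n = 5). Atoh1a (0.26 ± 0.19), lfng (-0.71 ± 0.28) and pcna (0.25 ± 0.26) were not called at 11 h. There were 770 calls (602 higher, 168 lower), 434 in all 4 fits (282 higher, 152 lower). With array medians set equal the higher share went from 78.2% to 66.6% (443 higher, 222 lower), and the count was 405 and 425 without untreated replicates 4 and 5, and 360 without replicate 1 at 11 h. With the close untreated pairs averaged it was 500.

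**Figure D3:**
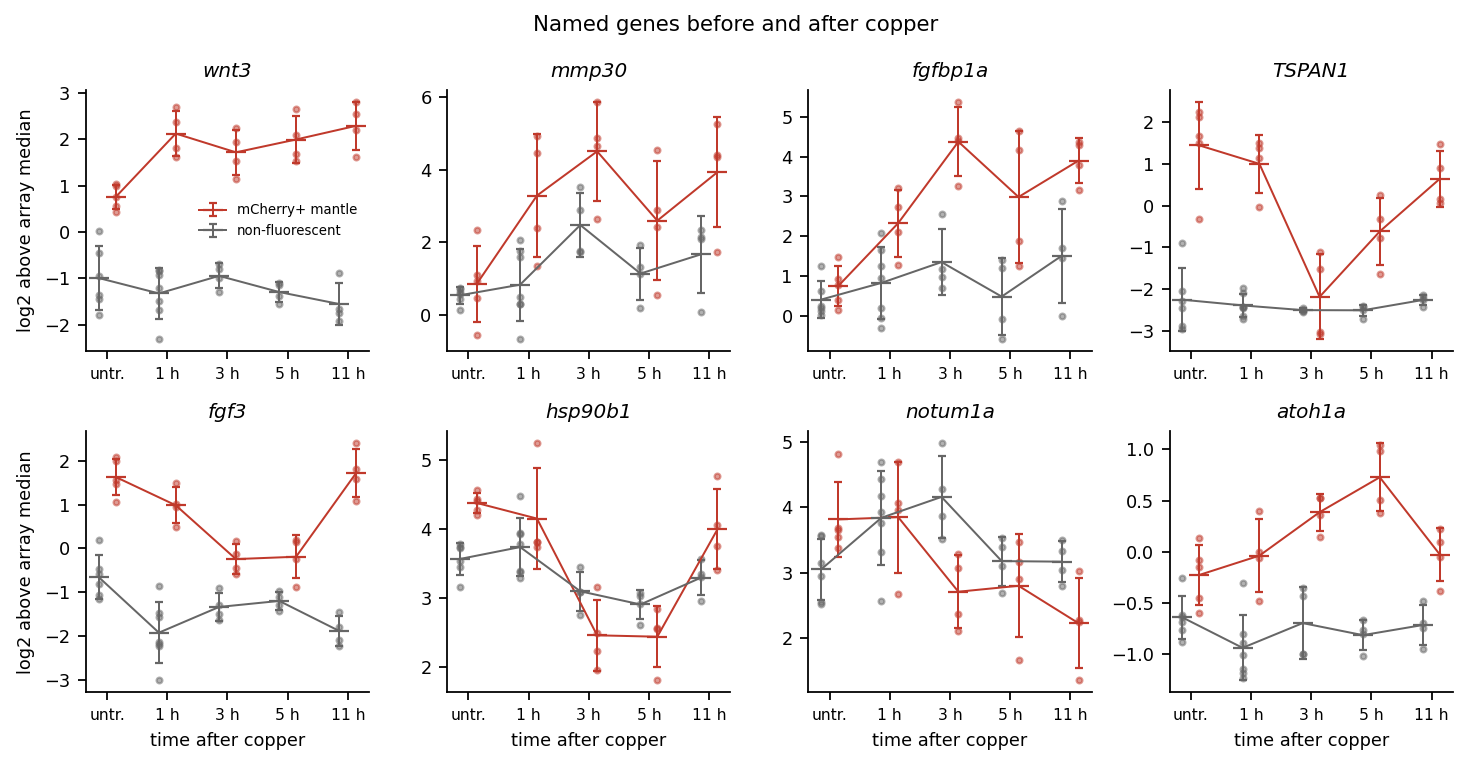
Log2 level above the array's median over the tested genes (vertical axis) of 8 named genes in untreated cells and 1 h, 3 h, 5 h and 11 h after copper (horizontal axis). The genes were chosen for the plot after their values were seen. Points are arrays, bars the mean ± SD, and lines join the means; wnt3 in mantle cells had a mean of 0.75 untreated and 2.29 at 11 h.

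In non-fluorescent cells the median of all genes moved by -0.197 at 1 h with array medians set equal, and changes are given relative to it. At that time (n = 7), 3 hair cell genes were lower than in untreated cells (n = 6), namely cabp2b, a calcium sensor (-1.15 ± 0.24), tekt3 (-0.95 ± 0.17) and otofb (-0.83 ± 0.17). Of 38 hair cell genes, 3 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.000477, adjusted p = 0.159 with an estimated correlation). The antioxidant genes gpx1a, a glutathione peroxidase (-1.46 ± 0.35), and cat, which encodes catalase (-0.86 ± 0.22), were lower, and the metal and oxidative stress list had 4 lower and 1 higher of 39 (4 and 2 adjusted over the list alone; camera adjusted p = 0.000477, adjusted p = 0.159 with an estimated correlation). Among the higher genes were twist2, a mesenchymal factor (1.71 ± 0.32), thbs1a, a thrombospondin (1.59 ± 0.32), and col6a1 (0.95 ± 0.17). Connective tissue genes were higher in 17 of 34 and lower in 0 (26 and 0 adjusted over the list alone; camera adjusted p = 5.9e-10, adjusted p = 0.149 with an estimated correlation), and 3 were higher in all 4 fits. Their mean was 8.67 ± 0.21 (n = 7) against 7.95 ± 0.22 (n = 6) on the deposited scale. Schwann cell and glia genes were higher in 5 of 16 (8 adjusted over the list alone; camera adjusted p = 0.00391, adjusted p = 0.176 with an estimated correlation), with mbpa at 1.42 ± 0.39. Leukocyte genes were lower in 2 of 31, also adjusted over the list alone (camera adjusted p = 7.38e-10, adjusted p = 0.176 with an estimated correlation), including the macrophage gene mpeg1.1 (-1.49 ± 0.28). Erythrocyte genes were lower in 2 of 16 (8 adjusted over the list alone; camera adjusted p = 1.11e-09, adjusted p = 0.189 with an estimated correlation). On the deposited scale the erythrocyte mean at 1 h was 2.99 and 3.10 in replicates 4 and 5 and 5.43 to 7.29 in the other 5 arrays. In untreated cells it was 4.66 to 5.06 in replicates 1 to 3 and 6.90 to 7.62 in replicates 4 to 6. The leukocyte mean at 1 h was 4.16 and 3.66 in replicates 4 and 5 and 4.70 to 5.81 in the others, against 4.40 to 4.71 in untreated replicates 1 to 3 and 5.47 to 6.09 in 4 to 6. Fgf3 was lower, at -1.27 ± 0.25 and lfng higher by 0.94 ± 0.23. The deposited values gave 2202 calls, 91.8% of them higher (2021 higher, 181 lower). With array medians set equal there were 959 calls, 48.3% higher (463 and 496), and 511 stood in all 4 fits (330 and 181).

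At 3 h non-fluorescent cells (n = 4) held more nrgna, a calmodulin-binding protein (3.85 ± 0.28), the ferritin gene fthl28 (3.34 ± 0.67), the mucin gene muc5.1 (2.30 ± 0.46) and gldn, a protein of myelinated nerves (2.30 ± 0.44), than untreated cells (n = 6). Gata2a, a transcription factor, was higher by 1.98 ± 0.25 and the integrin gene itga6b by 1.59 ± 0.31. Lower were egr3, an early response factor (-2.51 ± 0.50), rab35a, a membrane traffic GTPase (-2.43 ± 0.29), the Notch ligand dld (-1.38 ± 0.22) and rrm1 (-1.27 ± 0.25). Matrix remodelling genes were higher in 16 of 43 and lower in 0 (20 and 0 adjusted over the list alone; camera adjusted p = 0.00342, adjusted p = 0.538 with an estimated correlation). Wnt pathway genes were higher in 15 of 48 (19 adjusted over the list alone; camera adjusted p = 0.0145, adjusted p = 0.538 with an estimated correlation), of which 1, the receptor gene fzd2 (1.18 ± 0.21), stood in all 4 fits. For connective tissue the numbers were 16 higher and 1 lower of 34, also adjusted over the list alone (camera adjusted p = 0.00288, adjusted p = 0.538 with an estimated correlation), with prrx1b at 0.97 ± 0.20. Their mean was 8.46 ± 0.21 (n = 4) against 7.95 ± 0.22 (n = 6). The median of all genes moved by -0.102. Calls numbered 4600 (72.3% higher; 3327 higher, 1273 lower), 3695 with array medians set equal (56.1% higher; 2074 and 1621), 734 with the block and 506 in all 4 fits (317 and 189).

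At 5 h the same population (n = 4) was again higher in nrgna (2.93 ± 0.28) and muc5.1 (2.63 ± 0.46) than untreated cells (n = 6), and pus7l, a pseudouridine synthase, was higher by 3.79 ± 0.58. Mucous cell genes were higher in 5 of 9 (6 adjusted over the list alone; camera adjusted p = 0.0453, adjusted p = 0.706 with an estimated correlation). Cell cycle genes were lower in 7 of 45, also adjusted over the list alone (camera adjusted p = 0.000179, adjusted p = 0.706 with an estimated correlation), and mcm4 was lower, at -1.67 ± 0.29. Glia genes were higher in 7 of 16 and lower in 0 (8 and 0 adjusted over the list alone; camera adjusted p = 0.0453, adjusted p = 0.706 with an estimated correlation), with none in all 4 fits (0 genes). Rasl11b, a Ras-like GTPase, was lower, at -2.40 ± 0.40. The median of all genes moved by -0.106, and the calls were 3154 (78.8% higher; 2485 higher, 669 lower), 2248 with array medians set equal (59.5% higher; 1337 and 911), 234 with the block and 141 in all 4 fits (107 and 34).

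By 11 h non-fluorescent cells (n = 4) were higher than untreated cells (n = 6) in fthl28 (3.81 ± 0.67), aplnra (2.77 ± 0.59), the homeobox gene msx2a (1.99 ± 0.40) and the small heat shock gene hspb1 (1.77 ± 0.44). Cdkn1a, a cell cycle inhibitor that p53 induces, was higher by 1.2 ± 0.33 and the Notch ligand jag2b by 1.53 ± 0.29. Lower were atp1a1a.3, a sodium pump subunit (-2.71 ± 0.60), the DNA repair gene xpc (-1.70 ± 0.38) and fgf3 (-1.23 ± 0.30). In the connective tissue list 2 of 34 were higher (6 adjusted over the list alone; camera adjusted p = 0.0314, adjusted p = 0.81 with an estimated correlation). Atoh1a (-0.07 ± 0.18), sox2 (-0.73 ± 0.33), lef1 (-0.51 ± 0.22) and mmp9 (0.45 ± 0.72) were not called. The median of all genes moved by -0.143. There were 1673 calls (90.8% higher; 1519 higher, 154 lower), 977 without replicate 1 at 11 h, 618 with array medians set equal (62.8% higher; 388 and 230), and 409 in all 4 fits (273 and 136).

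**Figure D4:**
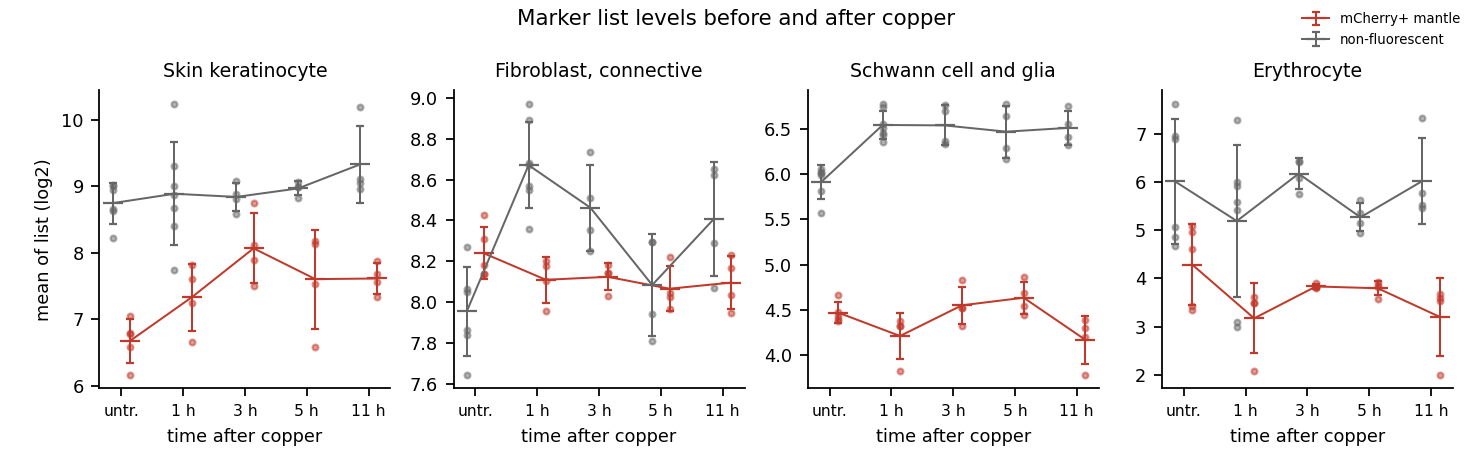
Mean log2 level of 4 marker lists (vertical axis) in untreated cells and 1 h, 3 h, 5 h and 11 h after copper (horizontal axis), with points for arrays, bars for the mean ± SD and lines joining the means. The keratinocyte list in mantle cells had a mean of 6.68 untreated and 8.07 at 3 h.

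Whether copper changed mantle cells differently from the other skin cells was tested as the difference of the responses, in mantle cells (n = 4 treated, 5 untreated) minus non-fluorescent cells (n = 7 treated at 1 h, 6 untreated), relative to the array medians. At 1 h the response of wnt3 was higher in mantle cells by 1.70 ± 0.41, that of the epidermal and neural crest factor tfap2a by 1.72 ± 0.43 and that of becn1, an autophagy gene, by 2.05 ± 0.45. Responses were lower in mantle cells for twist2 (-2.62 ± 0.50), the myelin gene mag (-2.60 ± 0.46), sox10 (-1.33 ± 0.30), egr2b (-1.80 ± 0.40), and vim, which encodes vimentin (-1.54 ± 0.32). These genes were dim in mantle cells on the deposited scale, at 3.90 (mag) to 4.59 (sox10) untreated and 3.00 (mag) to 3.86 (sox10) at 1 h. The median of the tested genes was 4.67 to 4.71 in untreated mantle arrays. Such a difference can come from a rise in non-fluorescent cells, where twist2 was higher at 1 h. The connective tissue list had 7 lower and 0 higher of 34 (17 and 0 adjusted over the list alone; camera adjusted p = 2.64e-09, adjusted p = 0.0695 with an estimated correlation). Glia genes were lower in 4 of 16 (7 adjusted over the list alone; camera adjusted p = 0.000107, adjusted p = 0.0695 with an estimated correlation), and pigment cell genes in 2 of 21 (5 adjusted over the list alone; camera adjusted p = 0.000357, adjusted p = 0.0695 with an estimated correlation). The median of all genes moved by 0.167. There were 428 calls (14.3% higher; 61 higher, 367 lower), 281 with array medians set equal (42.3% higher; 119 and 162) and 151 in all 4 fits (49 and 102). Without non-fluorescent untreated replicate 3, mantle untreated replicate 5 or mantle replicate 4 at 1 h, the count was 283, 229 or 211.

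At 3 h (n = 4 treated in each population) the response was lower in mantle cells for TSPAN1 (-3.36 ± 0.58), alpl (-2.51 ± 0.42), gata2a (-2.63 ± 0.36), sfrp2 (-2.59 ± 0.41) and the proliferation gene MKI67 (-2.75 ± 0.48), and higher for kitlgb, a ligand of the Kit receptor (3.72 ± 0.57). Gata2a was dim in untreated mantle cells, at 4.30 on the deposited scale, and was higher in non-fluorescent cells at 3 h. Keratinocyte genes responded more in mantle cells in 11 of 35 and less in 0 (13 and 0 adjusted over the list alone; camera adjusted p = 4.63e-09, adjusted p = 0.607 with an estimated correlation), with none in all 4 fits (0 genes). Connective tissue genes were lower in 12 of 34 (15 adjusted over the list alone; camera adjusted p = 0.0011, adjusted p = 0.607 with an estimated correlation), and Wnt pathway genes in 12 of 48 (18 adjusted over the list alone; camera adjusted p = 0.00353, adjusted p = 0.607 with an estimated correlation). Fgfr1a (-1.32 ± 0.27), lfng (-1.52 ± 0.39) and notch3 (-1.15 ± 0.29) were called on the deposited values, but with array medians set equal plus the block their adjusted p was 0.0972, 0.19 and 0.177. The total was 2736 (33.3% higher; 912 higher, 1824 lower), 2434 with array medians set equal (46.4% higher; 1130 and 1304), 136 with the block and 91 in all 4 fits (39 and 52).

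At 5 h (n = 4 treated in each population) the response of atoh1a was higher in mantle cells by 1.13 ± 0.27 (adjusted p = 0.0104; 0.372 with array medians set equal plus the block). Limma called 1319 genes (22.7% higher; 300 higher, 1019 lower; 4396 at an unadjusted p under 0.05), 869 without mantle untreated replicate 5, and 906 with array medians set equal (40.3% higher; 365 and 541). With the block on the deposited values there were 4, all lower, and 0 stood in all 4 fits. The named genes among these, chosen after their values were seen, were atmin (-3.73 ± 0.51 on the deposited scale), katna1 (-2.38 ± 0.33) and pphln1 (-1.91 ± 0.24). The keratinocyte list had 0 higher and 0 lower of 35, also adjusted over the list alone (camera adjusted p = 3.66e-05, adjusted p = 0.87 with an estimated correlation). The median of all genes moved by 0.121.

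At 11 h (n = 4 treated in each population) the response of wnt3 was again higher in mantle cells (2.1 ± 0.43), as were those of becn1 (2.37 ± 0.48) and of the transcription factor genes sox1a (2.07 ± 0.38) and foxg1c (2.03 ± 0.36). Responses were lower in mantle cells for cldn19 (-3.84 ± 0.71), gldn (-2.82 ± 0.64), mag (-2.66 ± 0.49), gata2a (-2.30 ± 0.36), sfrp2 (-1.97 ± 0.41) and col6a1 (-1.3 ± 0.28). In untreated mantle cells gldn, mag and gata2a were dim, at 3.59, 3.90 and 4.30 on the deposited scale. Non-fluorescent cells at 11 h were higher in gldn (1.93 ± 0.44) and gata2a (1.44 ± 0.25) relative to the array medians. Glia genes were lower in 3 of 16 (9 adjusted over the list alone; camera adjusted p = 0.000906, adjusted p = 0.138 with an estimated correlation), and connective tissue genes in 2 of 34 (6 adjusted over the list alone; camera adjusted p = 0.000906, adjusted p = 0.456 with an estimated correlation). Calls numbered 250 (19.6% higher; 49 higher, 201 lower), 96 with array medians set equal (36.5% higher; 35 and 61) and 68 in all 4 fits (27 and 41). The count was 147, 103 and 161 without non-fluorescent untreated replicates 2, 3 and 5. It was 152 without each of mantle untreated replicates 1 to 4, 96 without replicate 5, and 161 and 144 without mantle replicates 1 and 2 at 11 h. With the close untreated pairs averaged it was 118.

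The changes at different times were correlated across genes, which are not independent replicates. All times are set against the same untreated arrays, so each r is given beside the r from simulations of unchanged groups set against the same controls. The simulated groups hold no offset between treated and untreated arrays and no earlier adjustment, and splitting the untreated arrays removes neither. An r or covariance above the simulated one therefore cannot be read as a copper response alone. In mantle cells r was 0.66 between 1 h and 11 h (0.44 simulated; 0.49 with the untreated arrays split between the times) and 0.80 between 3 h and 5 h (0.44; 0.68). In non-fluorescent cells it was 0.52 between 1 h and 11 h (0.46; 0.30) and 0.70 between 3 h and 5 h (0.40; 0.56). In the other 8 pairs r was 0.16 to 0.42, under the simulated 0.40 to 0.47 of the same pair, and 0.02 to 0.32 with split controls. The covariance exceeded the simulated one in each pair but non-fluorescent 1 h and 5 h (0.0304 against 0.033), where 452 genes were called higher at both times, 23 lower at both and 68 in opposite directions. In mantle cells 96 genes were higher and 28 lower at both 1 h and 11 h, with 0 in opposite directions. Between the populations r was 0.08 at 1 h, 0.13 at 3 h, 0.27 at 5 h and 0.22 at 11 h. At 1 h 48 genes were higher in both (23.2 by independence), at 3 h 386 (266), at 5 h 277 (145) and at 11 h 101 (47.5). Lower in both were 5 (0.639), 184 (88.5), 148 (43.8) and 8 (1.34), while 9, 153, 61 and 8 were lower in mantle and higher in non-fluorescent cells and 0, 63, 10 and 2 the other way round.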

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

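The explanations for the patterns here were tested after the patterns were seen, except the test for connective tissue type cells and the splits of the samples, which were written before. The check of that test on separate arrays was added after its result was seen.

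Of 77 groups of list means or medians of the tested genes, 10 held an array with a gap to its nearest neighbour that was large against the group's range. All 10 were list means. Chance picks about 1 in 20 groups, but the same arrays recur across lists, so the groups are not independent. The neuromast list mean was 6.58 in untreated mCherry+ mantle replicate 5 (others 6.45 to 6.48) and 5.95 in non-fluorescent 11 h replicate 2 (5.86 to 5.87). Non-fluorescent 11 h replicate 4 stood apart in the keratinocyte list at 10.19 (8.95 to 9.11), in the muscle list at 6.33 (5.81 to 5.83) and in the erythrocyte list at 7.33 (5.45 to 5.76). Mantle 11 h replicate 4 stood apart in the muscle list at 3.27 (3.89 to 4.02) and in the erythrocyte list at 2.0 (3.53 to 3.68). The erythrocyte list was also at 2.25 in double-positive replicate 4 (4.42 to 4.66), at 2.08 in mantle 1 h replicate 4 (3.49 to 3.62) and at 3.9 in mantle 3 h replicate 3 (3.8 to 3.81).

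The copper response differed between mantle and non-fluorescent cells, by a test of the difference itself, in 428 genes at 1 h, 2736 at 3 h, 1319 at 5 h and 250 at 11 h. With the block for the earlier adjustment the counts were 314, 136, 4 and 119, and in all 4 fits 151, 91, 0 and 68 (limma, with 4396 genes at an unadjusted p under 0.05 at 5 h on the deposited values). The treated arrays of the populations also lie in separate sets, with array means of 4.45 to 4.48 in non-fluorescent and 4.29 to 4.37 in mantle cells. A difference of responses therefore cannot be separated from a difference of these sets.

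In both populations the 3 h and 5 h arrays lay apart from the 1 h and 11 h arrays. A possible technical explanation is that the 3 h and 5 h levels are tied to the other arrays through replicate 4 alone. Over the dimmest probe sets the spread of these differences, relative to independent arrays, was 1.5 times that of comparisons not tied this way, which that explanation predicts. It does not account for all of the spread, since the tie would give ratios to independent arrays of 1.32 to 1.40, where the observed ones were 1.55 to 1.89, and 1.07 to 1.15 in comparisons not tied. A processing step shared by both populations could not be told from its absence, since the differences of the populations correlated at 0.02 over the dimmest probe sets and at 0.13 over all. A copper response largest at these times may also contribute, as 122 genes stayed called between 3 h and 1 h in mantle cells with the block, but the labels name no batch and this cannot be told.

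Treated arrays lay apart from untreated ones at both 1 h and 11 h. A possible explanation is that they were normalized apart: the spread of treated minus untreated means over dim probe sets, relative to independent arrays, was 1.29 times that of 11 h against 1 h, which it predicts. A copper response that lasts to 11 h may contribute too. The covariance of the changes at these times in mantle cells was 0.0986 with the untreated arrays split. An offset that the treated arrays share would also give a positive covariance, so this value does not tell the explanations apart. The labels say that the copper analysis was imported separately, which goes with normalization apart. They do not say which arrays were normalized together, so the share of each explanation cannot be told.

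Connective tissue genes were lower and neuromast genes higher in double-positive than in mCherry+ mantle cells. Non-fluorescent cells carried into the mCherry+ sort would bring keratinocyte genes with them. The keratinocyte list was instead higher in double-positive cells, with a median of 1.15, the other way from that prediction. Whether double-positive cells express these genes themselves or carry skin cells was not tested, so this does not decide. Carry-over of connective tissue cells alone was not tested either. Connective tissue type cells within the mCherry+ gate stay open as a possible explanation. Of 23 connective tissue genes lower in double-positive cells, 9 were higher in mCherry+ than in non-fluorescent cells, 2 lower and 12 not called. The same mCherry+ arrays chose and tested these genes, so the arrays were also parted, with 3 choosing and 2 tested, in 10 ways. Then 34.8% to 42.9% of the chosen list genes were higher, and 41.5% to 48.5% of all genes chosen the same way. The list did not exceed all genes in any of the 10, so the count does not decide. The whole list had 12 higher and 9 lower of 34 in mCherry+ against non-fluorescent cells.

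For each of the 3 tested untreated comparisons, 1 of 100 groupings of the arrays, the real one, called as many genes. That is the lowest share possible here, as the real grouping is always counted. The splits treat arrays as independent, which the close untreated pairs may not be. The highest other counts were 4058 for mCherry+ against non-fluorescent, 1720 for double-positive against non-fluorescent and 2312 for double-positive against mCherry+ cells. For copper against untreated cells it was again 1 of 100 at each time, with highest other counts of 10, 1281, 750 and 250 in mantle cells and 253, 520, 202 and 173 in non-fluorescent cells at 1, 3, 5 and 11 h. For the differences of responses it was 1 of 100, with 42, 733, 519 and 91. In both kinds of comparison any other split mixes treated and untreated arrays, which lie in separate sets. These splits therefore cannot tell a copper response from a difference of the sets. Within treated mantle cells the real grouping was 1 of 35 for 3 h against 1 h (highest other count 1) and for 5 h against 1 h (2). Such splits, here and in non-fluorescent cells, mix the arrays of the earlier adjustment with the 1 h arrays. In simulated mantle arrays with no changed gene that adjustment alone gave 74 calls between 3 h and 1 h, against 2071 in the data. As the splits mix time and adjustment together, they cannot tell a change over time from the adjustment, whatever the share of each. For 11 h against 1 h and 5 h against 3 h limma called 0 genes (1687 and 1420 at an unadjusted p under 0.05). All 35 of 35 splits call at least 0 by construction (highest 2 and 5), so the splits say nothing about these comparisons. Within treated non-fluorescent cells it was 1 of 100 for 3 h against 1 h (45) and for 5 h against 1 h (223). For 11 h against 1 h 4 of 100 groupings called as many as the real 16, and 1 called 356, which points to a structure of the samples that was not tested. For 5 h against 3 h 4 of 35 called as many (highest 2), so chance was not excluded. The hair cell comparisons, with 2 hair cell arrays, were not tested this way.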

How the results depend on the processing

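The block for the earlier adjustment, that block with centring, the averaged close pairs and the comparisons within treated arrays were added after the data were seen. Counts that moved by more than 1.5 times are given per setting, and the cause was not tested, except that a stricter threshold, or fewer or more features, lowers or raises counts by construction. NF stands for non-fluorescent cells, and 3v1 h for 3 h against 1 h. Of 1051 named-gene calls, 0 reversed under the settings run, where 963 of them were tested with dim genes left out. They lost their call in 116 cases with centring, 146 with quantile normalization and 438 with the block and centring, always in the same direction. Of 156 list calls, 137 were lost with an estimated correlation and 19 kept. The ribosomal protein list reversed under quantile normalization, with medians of -0.033, -0.075 and -0.127 in mantle cells at 1, 3 and 11 h and of -0.076 and -0.176 in NF at 1 and 11 h. None of these 5 passed in both settings: mantle 1 and 3 h and NF 1 h passed on the deposited values alone, and both 11 h ones under quantile normalization alone (adjusted p = 0.00448 and 2.6e-05). The endothelium list of the difference at 11 h turned its camera direction with dim members left out (median -0.403 against -0.328; adjusted p = 0.971 against 0.0476). The cause was not tested.

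All probe sets in place of named genes gave 13297 (mCherry+/NF), 14050 (double/NF), 15706 (hair/NF), 15637 (hair/mCherry+) and 12383 (double/mCherry+); mantle 2172 (1 h), 11401 (3 h), 10687 (5 h) and 3307 (11 h). Also NF 9485 (1 h), 17737 (3 h), 14833 (5 h) and 8094 (11 h), difference 2078 (1 h), 9615 (3 h), 6060 (5 h) and 1980 (11 h), mantle within 5814 (3v1 h) and 5830 (5v1 h), NF within 9491 (3v1 h), 8677 (5v1 h), 53 (11v1 h) and 14 (5v3 h). An adjusted p below 0.01 gave 3959 (double/NF) and 3026 (double/mCherry+); mantle 54 (1 h), 1294 (3 h), 972 (5 h) and 209 (11 h). Also NF 807 (1 h), 2249 (3 h), 1381 (5 h) and 428 (11 h), difference 106 (1 h), 1111 (3 h), 321 (5 h) and 18 (11 h), mantle within 645 (3v1 h) and 615 (5v1 h), NF within 1238 (3v1 h), 1074 (5v1 h), 0 (11v1 h) and 0 (5v3 h). Leaving out dim genes gave mantle 1583 (5 h); NF 1180 (1 h), 2342 (3 h), 1369 (5 h) and 590 (11 h). Also difference 258 (1 h), 866 (5 h) and 129 (11 h), mantle within 1 (11v1 h), NF within 9 (11v1 h) and 0 (5v3 h). Quantile normalization gave mantle 139 (1 h); NF 841 (1 h) and 770 (11 h). Also difference 198 (1 h) and 112 (11 h), NF within 3 (11v1 h) and 2 (5v3 h). Array median centring gave NF 959 (1 h) and 618 (11 h); difference 281 (1 h) and 96 (11 h). Also mantle within 7 (11v1 h). Array weights gave mantle 925 (1 h), 4805 (3 h) and 3872 (5 h); NF 6063 (5 h) and 965 (11 h). Also difference 779 (1 h), 4232 (3 h), 3079 (5 h) and 140 (11 h), mantle within 6 (5v3 h), NF within 4228 (5v1 h), 0 (11v1 h) and 280 (5v3 h). Only the groups compared gave mantle 450 (1 h); NF 1452 (1 h) and 388 (11 h). Also difference 2382 (5 h) and 141 (11 h), NF within 0 (11v1 h) and 71 (5v3 h). No variance moderation gave mantle within 2 (11v1 h); NF within 31 (11v1 h) and 3 (5v3 h). All 52 arrays in 1 fit gave mantle within 26 (11v1 h) and 3 (5v3 h); NF within 433 (11v1 h) and 193 (5v3 h). The mean of probe sets gave mantle within 6 (11v1 h). The block for an earlier adjustment gave 2552 (double/mCherry+); mantle 174 (1 h), 360 (3 h) and 137 (5 h). Also NF 734 (3 h) and 234 (5 h), difference 136 (3 h), 4 (5 h) and 119 (11 h), mantle within 122 (3v1 h) and 133 (5v1 h), NF within 247 (3v1 h), 211 (5v1 h) and 0 (5v3 h). That block with centring gave 2631 (double/mCherry+); mantle 123 (1 h), 360 (3 h), 135 (5 h) and 504 (11 h). Also NF 724 (1 h), 506 (3 h), 141 (5 h) and 440 (11 h), difference 193 (1 h), 91 (3 h), 0 (5 h) and 71 (11 h), mantle within 111 (3v1 h) and 64 (5v1 h), NF within 236 (3v1 h), 189 (5v1 h), 0 (11v1 h) and 0 (5v3 h). Averaging the close untreated pairs gave mantle 144 (1 h) and 500 (11 h); difference 118 (11 h).

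The replicate numbers were checked as pairs: of 21 same-number pairs 3 correlated above 0.1 (-0.03 to 0.28) and 11 correlated best with their own number, among them all 4 at 3 h and 3 of 4 at 5 h. The labels state no pairing and most pairs stayed below 0.1, so no pairing was assumed, and it is left open. The closest untreated pairs were NF replicates 5 and 6 (SD of their difference 0.34, median pair 0.59) and mCherry+ replicates 1 and 2 (0.42, median pair 0.53). The 2 hair cell arrays were nearly as close (0.43, r = 0.976), with no other pair to set against. The labels do not say whether the arrays of these pairs are separate samples. With the replicate block the counts were mantle 130 (1 h) and 474 (11 h); NF within 1208 (3v1 h), 1012 (5v1 h), 1 (11v1 h) and 0 (5v3 h). Leaving out 1 array at a time gave untreated 5448 to 6181 (mCherry+/NF), 5490 to 6207 (double/NF), 4637 to 7033 (hair/NF), 4919 to 6583 (hair/mCherry+) and 4145 to 4882 (double/mCherry+). Ranges for mantle 108 to 264 (1 h), 2040 to 2575 (3 h), 1541 to 2117 (5 h) and 360 to 683 (11 h). Ranges for NF 1637 to 2371 (1 h), 3518 to 4449 (3 h), 2150 to 2965 (5 h) and 977 to 1702 (11 h). Ranges for difference 211 to 531 (1 h), 2133 to 2816 (3 h), 869 to 1243 (5 h) and 96 to 341 (11 h). Ranges for mantle within 1325 to 1614 (3v1 h), 1252 to 1614 (5v1 h), 0 to 1 (11v1 h) and 0 to 0 (5v3 h). Ranges for NF within 1954 to 3168 (3v1 h), 1593 to 2744 (5v1 h), 2 to 67 (11v1 h) and 0 to 6 (5v3 h). Where 1 hair cell array was left, it was assumed to vary like the other groups.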

Other observations

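Further gene lists were compared between the untreated populations. Ionocyte genes, which mark the ion-transporting cells of skin, were lower in mCherry+ mantle cells (n = 5) than in non-fluorescent cells (n = 6) in 11 of 20 and higher in 0 (12 and 1 adjusted over the list alone; camera adjusted p = 0.000199, adjusted p = 0.109 with an estimated correlation). The carbonic anhydrase gene ca2 was lower, at -5.09 ± 0.32 and the anion exchanger gene slc4a1b, at -3.68 ± 0.15, relative to the array medians. Immediate early genes were lower in 20 of 40 and higher in 2, also adjusted over the list alone (camera adjusted p = 0.000257, adjusted p = 0.201 with an estimated correlation), with klf2b at -3.05 ± 0.33. Endothelial genes were lower in 16 of 27 and higher in 1, also adjusted over the list alone (camera adjusted p = 0.000199, adjusted p = 0.101 with an estimated correlation), with the receptor gene kdrl at -2.31 ± 0.23. The inflammation list did not pass the test, with 4 higher and 12 lower of 42 (camera adjusted p = 0.0641), though the cyclooxygenase gene ptgs2b was lower, at -4.44 ± 0.35. The neuron list had 4 higher and 3 lower of 31 (camera adjusted p = 0.877), and the p53 list 5 and 13 of 31 (camera adjusted p = 0.0244, adjusted p = 0.193 with an estimated correlation).

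Hair cells (n = 2) held more of the synaptic gene vamp2 (3.76 ± 0.48) and of isl2a, a neuronal factor (3.76 ± 0.29), than non-fluorescent cells (n = 6), while the neuron list as a whole had 6 higher and 6 lower of 31 (camera adjusted p = 0.948). At 1 h after copper, endothelial genes in non-fluorescent cells (n = 7 and 6) were higher in 10 of 27 (12 adjusted over the list alone, camera adjusted p = 6.48e-05, adjusted p = 0.176 with an estimated correlation). Flt4, a receptor of lymphatic growth factors, was at 0.81 ± 0.22 relative to the array medians. On the deposited scale the endothelial mean at 1 h was 5.55 in replicate 4 and 5.15 and 5.07 in replicates 1 and 5. It was 4.69 to 4.78 in the other 1 h arrays, against 4.25 to 4.59 in untreated arrays.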
